A study of Mus musculus with 2 samples.

How the data were processed

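The 2 libraries are long-read RNA sequencing of hippocampus tissue from male B6CASTF1/J mice, and each has a table of transcript models with a read count and an annotation of the models' exons. The deposited values are raw read counts per transcript model, 1 library per table, and list only models with at least 1 read. The authors mapped to mm10 with GENCODE annotation M21, per the deposited notes to the files, and derived the counts from a filtered alignment. The source field of the deposited annotation names TALON, a program that assigns long reads to annotated or new transcript models, for every model outside the annotation. The aligner, its version and the read filters are not given in the sources used here. Spike-ins were added per the labels, the Ambion mix and a set of SIRVs, and no SIRV model was among those with reads. The models hold lengths down to under 50 bases, 1081 models with 12181 reads in replicate 1 and 998 with 7323 in replicate 2, and they were kept.

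Because TALON ran on each library alone, its names for new models are not shared. Annotated transcripts were matched by identifier, new multi-exon models by chromosome, strand and every intron, and new single-exon models of a gene were pooled as fragments. Gene levels are CPM, the usual scaling of counts to a common library total, of reads assigned to annotated genes without spike-ins. Genomic models count toward genes and not toward transcript shares. Library totals, not TMM, scaled the main comparison. TMM moved it by 0.00 on the log2 scale and DESeq2 size factors by 0.01.

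With 1 library on each side no residual degrees of freedom remain, so the quasi-likelihood test of edgeR could not be fitted. Each gene with at least 10 reads in the sum was compared by an exact two-sided binomial test against the ratio of library totals. Genes with at least 20 reads in each library and more than a single transcript were compared by Fisher's exact test. It was applied to the share of the most-read transcript. Both tests had Benjamini-Hochberg adjustment at 0.05. These tests compare the 2 libraries and cover counting error, not the spread between animals. The labels give separate tissue samples and call them biological replicates, but both carry the same donor identifier, so it is not known here whether they came from separate animals. The SDs and dispersion then measure only the spread between these samples, which may be technical, and the binomial and Fisher p-values do not measure it. The common dispersion was estimated with edgeR 4.0.16 on TMM-scaled counts with an intercept only, and DESeq2 1.42.0 gave size factors, in R 4.3.3. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Log2 ratios use a pseudocount of 1 CPM. For each of 27 gene lists, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean CPM. Binomial intervals are exact at 95%.

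The tests were run on simulated data first. With 200 genes of at least 50 reads changed 2-fold, the gene test recovered 59.0% with 6 false calls among 11770 genes, and 95.5% at 4-fold with 9 false calls among 11816. With the main transcript share moved by 20 points in 200 of 6179 genes, Fisher's exact test recovered 36.0% with 3 false calls, and 81.5% at 40 points with 4 false calls. The simulated reads held counting error only, with no spread between libraries and no reads named for another gene. The counts of false calls therefore do not cover calls that arise in those ways.

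Gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 10 nuclear genes of highest mean CPM, up to 4 leading members of each list and its called members, the 5 genes higher in each library by ratio with at least 50 reads, up to 30 genes of an isoform list, the 5 largest changes of main transcript share in each direction, the 5 highest NIC and 5 highest NNC chains in both libraries, the 5 highest unannotated loci, and the 10 most-read genes with 2 annotated transcripts at 25 to 60% each. Some genes that the rule takes are not reported here, and fewer members are printed for some lists. Alternatives changed the reads counted, the scaling, the read minimum, the pseudocount and the transcripts counted. Counting multi-exon models only, leaving single-exon fragments out, and adding the common dispersion to counting error with TMM in edgeR's exact test were added after seeing the data.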

Results

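Long-read RNA sequencing was used to read transcripts from the hippocampus of male mice, 2 months old. The mice were of the B6CASTF1/J cross, a hybrid of C57BL/6J and CAST/EiJ. The labels give the tissue type of both samples as layer of hippocampus. The series holds 1 group of 2 biological replicates, labelled as tissue samples 5 (replicate 1) and 6 (replicate 2), each prepared from 2 µg of total RNA. There is no second condition, so the values describe the tissue and the comparison is between the 2 libraries. Replicate 1 held 1112491 reads assigned to transcript models and replicate 2 held 961793, of which 965057 and 844451 fell on annotated genes without spike-ins. At this depth a gene with 0 reads may still be present at up to 3.11 CPM (reads scaled to the same library total) in replicate 1 and 3.55 CPM in replicate 2, taking 3 counts as the limit. Intervals and limits cover counting error only. Coordinates are those of mouse assembly mm10.

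Most reads came from annotated transcripts of protein-coding genes. Annotated transcripts held 59.8% ± 0.557 of the reads (SD, n = 2), with 59.4% in replicate 1 (exact Clopper-Pearson 95% interval 59.4 to 59.5) and 60.2% in replicate 2 (60.1 to 60.3). Incomplete splice matches (ISM), which carry part of an annotated intron chain, held 10.6% ± 0.136. Chains that lack only their 5' part held 6.98% ± 0.140 of the reads and chains that lack only their 3' part 0.841% ± 0.0938. Multi-exon models joining annotated splice sites in an unannotated way (NIC) held 6.58% ± 0.0896, and models with at least 1 unannotated splice site (NNC) 3.74% ± 0.0865. Reads that overlap a gene without matching its transcripts, mostly of a single exon and called genomic, held 8.08% ± 0.0843. Reads on the strand opposite to a gene held 9.57% ± 0.668, and intergenic reads 1.61% ± 0.113. Antisense reads numbered 110306 in replicate 1 (exact interval of the share 9.98 to 10.1%) and 86203 in replicate 2 (9.04 to 9.15%), so the intervals do not overlap. Among reads of annotated genes, 97.4% ± 0.0775 were from protein-coding genes, 1.25% ± 0.0541 from long noncoding genes and 1.13% ± 0.0187 from pseudogenes. Mitochondrially encoded genes took 0.186% and 0.187% of the reads in replicates 1 and 2.

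**Figure D1:**
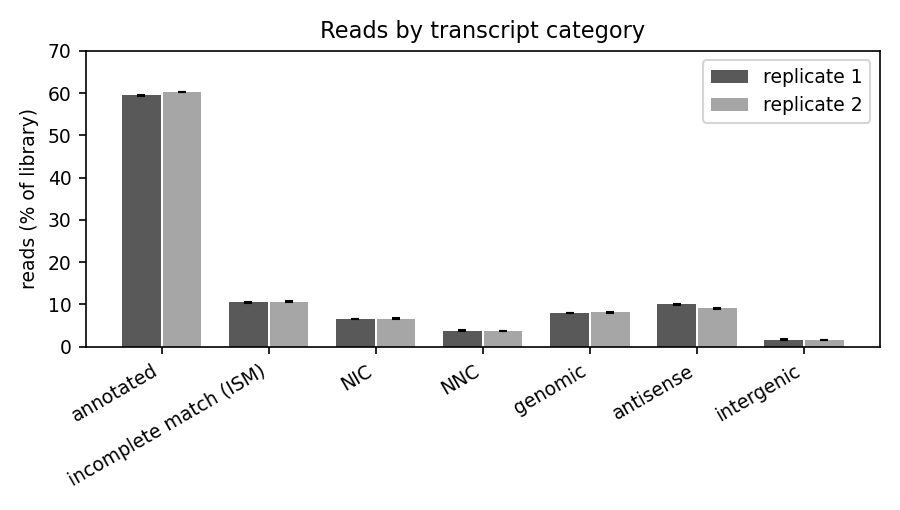
Reads in each transcript category as a percent of the library (y axis), for replicate 1 (dark) and replicate 2 (light), with exact 95% intervals as error bars. Annotated transcripts hold 59.4% and 60.2%, and NNC models are under 4% in both.

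Among the most abundant nuclear transcripts were those of calcium signalling, lipid transport and protein turnover. Apoe, the main lipoprotein of astrocytes, reached 5842 ± 394 CPM (SD, n = 2), Ncdn (neurochondrin) 4898 ± 251 and the polyubiquitin gene Ubb 4892 ± 156. High levels were also read for the autophagy gene Gabarapl1 at 4171 ± 453, the prohormone-processing enzyme Cpe at 3838 ± 331, Calm2, which encodes the calcium sensor calmodulin, at 3505 ± 207, ferritin heavy chain Fth1 at 3458 ± 122 and the glycolytic enzyme Aldoa at 3408 ± 67.2. Of the 3716 and 3792 reads of Gabarapl1 in replicates 1 and 2, only 403 and 406 were multi-exon. Its level therefore rests mainly on single-exon reads. The 10 highest genes together held 4.44% of the reads of annotated genes and the 100 highest 17.4%.

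Markers of every hippocampal subfield were read in both libraries, and none of their members passed the test between libraries. Of the dentate gyrus granule cell markers, 10 of 12 had enough reads to test, led by calbindin (Calb1) at 285 ± 5.02 CPM and C1ql2 at 194 ± 8.27. The median log2 ratio of this list (replicate 2 over replicate 1) was -0.08, at percentile 24.3 of random lists matched on expression, and -0.01 with multi-exon reads only. CA1 markers (11 tested) were led by Wfs1 at 341 ± 11.1 CPM, Ccn3 at 215 ± 18.8 and Mpped1 at 205 ± 23.2, with a median of -0.02 at percentile 40.4, and 0.12 at percentile 81.5 with multi-exon reads only. CA2 markers (7 tested) were led by Pcp4 at 346 ± 4.49 and Necab2 at 304 ± 1.79, with a median of -0.07 at percentile 30.8, and -0.01 with a minimum of 50 reads or -0.02 with multi-exon reads only. CA3 markers (9 tested) were led by Homer3 at 150 ± 24.9 and Bok at 140.5 ± 21.1, with a median of -0.14 at percentile 17.6, and -0.09 with a minimum of 50 reads. Among excitatory neuron genes (12 tested), Nrgn stood at 2137 ± 93.2 CPM and the vesicular glutamate transporter Slc17a7 at 1633 ± 152, and the list median was 0.12 at percentile 96.3. None of the 12 passed over all genes and 1 passed adjusted over the list alone. Inhibitory neuron genes (14 tested) included the neuropeptide gene Cck at 1074 ± 120 CPM and Gad1, which makes GABA, at 349 ± 4.61. None passed over all genes and 1 passed adjusted over the list alone, with a median of 0.01 at percentile 58.1, and -0.01 with multi-exon reads only.

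Glial and vascular genes were read in both libraries. Of 18 astrocyte genes tested, Apoe alone passed, also when adjusted over the list alone, at 0.14 on the log2 scale (exact binomial test, Benjamini-Hochberg adjusted p = 0.000433). Its exact 95% interval was 0.08 to 0.19 with all reads. With multi-exon reads only, the ratio was 0.08 (0.00 to 0.15) and did not pass, nor did Apoe pass with the common dispersion added. Aldoc stood at 1710 ± 95.2 CPM, the glutamate transporter Slc1a3 at 723 ± 18.9 and the gap junction gene Gja1 at 655 ± 17.2, and the list median was 0.00 at percentile 52.3, with -0.01 at a minimum of 50 reads and -0.02 with multi-exon reads only. Oligodendrocyte genes (15 tested) included the myelin gene Mbp at 1873 ± 113 and the transferrin gene Trf at 422 ± 50.9. None passed over all genes and 1 passed adjusted over the list alone, with a median of 0.02 at percentile 57.4. This median was -0.12 with a minimum of 50 reads and -0.13 with multi-exon reads only, at percentiles 8.27 and 6.02. Oligodendrocyte precursor genes (7 tested) stood lower, with Olig2 at 46.9 ± 2.62 CPM and Pdgfra at 34.2 ± 1.47, and a median of 0.19 at percentile 85.3, which turned to -0.09 at percentile 37.8 with a minimum of 50 reads and was 0.10 with multi-exon reads only. Microglial genes (12 tested, none called) included Csf1r at 94.7 ± 20.0. Their median was -0.25 at percentile 2.52, just inside the central 95% of random lists, and outside it with multi-exon reads only (-0.52) or a minimum of 50 reads. Endothelial and mural cell genes (11 tested) were led by Cldn5 at 197 ± 25.6, with a median of -0.01 at percentile 49.1, and 0.13 with multi-exon reads only.

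Among the genes of neighbouring tissue and of blood that were tested, Ttr alone passed over all genes. Of the 4 choroid plexus and ependymal genes with enough reads, Ttr, which encodes transthyretin, had 34 reads (35.2 CPM) in replicate 1 and 78 (92.4 CPM) in replicate 2 (exact binomial test, adjusted p = 0.000554). Enpp2 stood at 111 ± 8.16 CPM and the list median was 0.43 at percentile 97.1, and 0.76, outside the central 95%, with a minimum of 50 reads. At that minimum only Ttr (log2 ratio 1.37) and Enpp2 remained in the list, so its median then leans on Ttr. Ttr was also the only member to pass adjusted over the list alone. Blood genes (5 tested) were led by the hemoglobin gene Hba-a1 at 194 ± 21.5 CPM, which is uncertain because Hba-a2 is a near-identical copy, with a median of 0.13 at percentile 83.3. Thalamic markers (4 tested) were led by Prkcd at 51.0 ± 8.48 CPM, with a median of -0.24 at percentile 22.5, and -0.15 with multi-exon reads only. Striatal markers (5 tested) were led by Ppp1r1b at 66.9 ± 10.9, with a median of -0.33 at percentile 8.78, and neocortical markers (8 tested) by Lamp5 at 49.1 ± 2.41, with a median of 0.00 at percentile 55.8, with -0.04 at a minimum of 50 reads and 0.10 with multi-exon reads only. No member of the blood, thalamic, striatal and neocortical lists passed, over all genes or adjusted over the list alone.

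Of the genes of transmission tested, Camk2b alone passed over all genes. Synaptic vesicle and release genes (20 tested) summed to 14543 ± 53.9 CPM, with the membrane fusion genes Snap25 at 1956 ± 86.8, Nsf at 1477 ± 43.7 and Vamp2 at 1466 ± 7.15. None passed over all genes and 1 passed adjusted over the list alone, with a median of -0.02 at percentile 27.1, and 0.00 at percentile 58.8 with multi-exon reads only. Of 20 postsynaptic density genes, the kinase gene Camk2b passed, also adjusted over the list alone but not with the common dispersion added, at 1688 ± 188 CPM and a log2 ratio of 0.23 (exact binomial test, adjusted p = 0.00417). The exact 95% interval of this ratio was 0.12 to 0.33. With multi-exon reads only the ratio was 0.21 (0.10 to 0.32), and on these fewer reads the adjusted p of the exact test was 0.0764. The list median was 0.06 at percentile 85.9, and 0.12 at percentile 96.8 with a minimum of 50 reads. Ionotropic glutamate receptor genes (15 tested, none called) were led by Gria1 at 747 ± 79.0 CPM, Grin1 at 720.4 ± 76.5 and Gria2 at 582 ± 13.9. Their median was 0.15 at percentile 95.7, outside the central 95% with a minimum of 50 reads (0.19) and 0.09 with multi-exon reads only. GABA-A receptor genes (11 tested, none called) included Gabra5 at 251 ± 6.48, with a median of 0.05 at percentile 68.5.

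Among 14 immediate early genes tested, which are induced by neuronal activity, 2 passed in opposite directions, and the same number passed adjusted over the list alone. Arc had 50 reads in replicate 1 and 87 in replicate 2, a log2 ratio of 0.98 (exact binomial test, adjusted p = 0.0222), and kept its call with multi-exon reads but not with the spread shared by all genes added. Egr2 had 27 reads in replicate 1 and 0 in replicate 2, where 12 reads at the same place were named for an unannotated gene. Junb stood at 142 ± 3.24 CPM, and the list median was 0.11 at percentile 86.7. Glucocorticoid response genes (10 tested, none called) were led by Errfi1 at 141 ± 21.9 and Tsc22d3 at 108 ± 21.9, with a median of 0.06 at percentile 65.1. With a minimum of 50 reads this median was -0.35, outside the central 95%, and with multi-exon reads only 0.18. Circadian clock genes (15 tested, none called) were led by Tef at 351 ± 32.3 and Cry2 at 216 ± 11.7, with a median of -0.03 at percentile 39.1, and 0.01 with a minimum of 50 reads. Mitochondrially encoded protein genes (11 tested, none called) were led by mt-Co1 at 452 ± 24.6, with a median of 0.03 at percentile 62.1. Imprinted genes (12 tested) were led by Gnas at 1487 ± 120 and Snrpn at 1315 ± 132. None passed over all genes and 3 passed adjusted over the list alone, with a median of -0.03 at percentile 40.9. Brain long noncoding genes (13 tested, none called) included Meg3 at 403 ± 49.5 and Miat at 167 ± 31.2, with a median of -0.06 at percentile 27.9. Of the X inactivation and Y-linked genes (4 tested, none called), Ddx3y stood at 52.1 ± 8.37 CPM and Eif2s3y at 45.9 ± 11.3, while Xist had 0 reads in both male libraries. Their median was -0.08 at percentile 43.9, but -0.41 at percentile 3.74 with a minimum of 50 reads and -0.39 at percentile 7.36 with multi-exon reads only.

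Both libraries held reads of 15208 of the 18896 annotated genes seen in either. Across genes, which are not independent replicates, log2(CPM + 1) had a Pearson r of 0.946 and a Spearman rho of 0.943. The biological coefficient of variation, the spread between these samples beyond counting error, was 6.95% by edgeR. Of 11782 genes with at least 10 reads in the sum, 62 differed between the libraries (exact binomial test, adjusted p under 0.05), 32 higher in replicate 2 and 30 higher in replicate 1. With the common dispersion added to counting error and TMM scaling, chosen after seeing the data, 32 of the 62 passed (edgeR's exact test) and no other gene. With multi-exon reads only, a setting chosen after seeing the data, 21 of 10387 genes differed, and 18 of these were among the 62. Without genomic reads 134 of 10957 genes differed, 32 of the 62 among them, and with annotated transcripts only 18 of 9069, 14 of the 62 among them. Genes of high abundance that passed under both counts were Cox4i1, a subunit of respiratory complex IV (2516 ± 379 CPM, log2 ratio 0.31), Cpe (-0.18), Ywhah (-0.21), Cd81 (-0.35), Cyfip2 (0.43) and the chaperone gene Hspa5 (-0.45). These were chosen after their values were seen, and none of them passed when the common dispersion was added to counting error.

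At several of the genes with the largest ratios, single-exon reads at the same place carried another gene's name in the other library. Tcte1 had 0 reads in replicate 1 and 97 in replicate 2, and at its leading model (17:45541952-45544379) replicate 1 held 96 single-exon reads named for an unannotated gene. Wdr92 had 14 and 156 reads, and 150 reads at the same place in replicate 1 were named for Ppp3r1. Usp50 had 7 and 62 reads and shared its place with Gm10774. In the other direction, Efemp2 had 241 and 12 reads, with 143 single-exon reads at the overlapping Cfl1 in replicate 2. Mpp4 had 64 and 1, of which 3 and 1 were multi-exon reads, too few to test, and Gm49325 had 79 and 3, with 88 reads of Sumo3. Ap1g2 had 50 and 6 reads (log2 ratio -2.70) and BC065397 246 and 63 (-1.76), and both kept their calls with multi-exon reads only, at -2.70 and -2.09. Efemp2 kept its call with a smaller ratio, -2.14 (33 and 6 reads) against -4.04 with all reads.

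**Figure D2:**
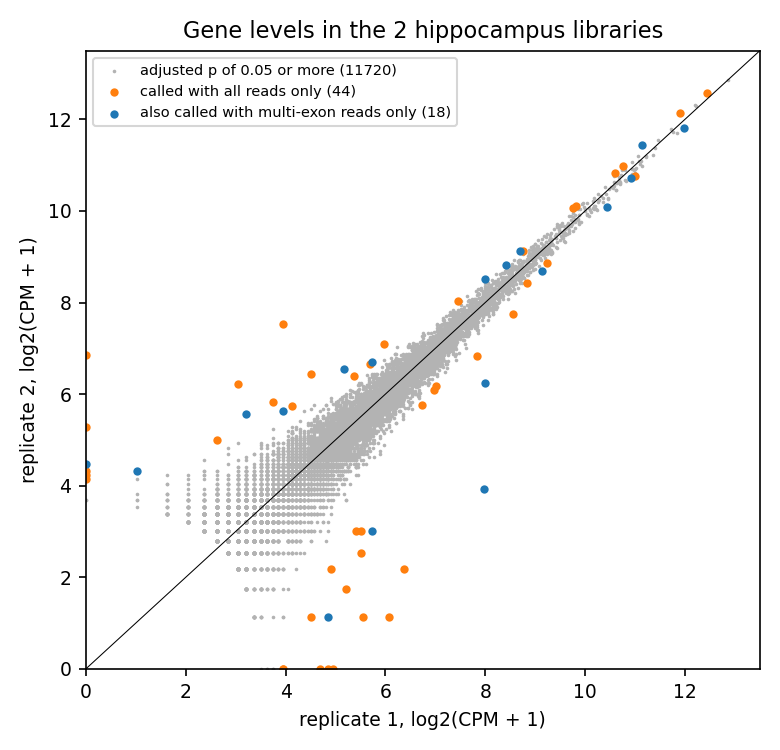
Level of each of 11782 genes in replicate 1 (x axis) and replicate 2 (y axis) as log2(CPM + 1), with the line of equal level. Grey points did not pass, orange points (44) passed with all reads only, and blue points (18) also passed with multi-exon reads only.

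Most genes had the same most-read transcript in both libraries. The 6179 genes compared had at least 20 reads in each library and more than a single transcript. Their most-read transcript held a median of 69.6% of the gene's reads in replicate 1 and 70.1% in replicate 2. It was the same transcript in both libraries for 93.2% of the genes (5759 genes, exact Clopper-Pearson interval 92.5 to 93.8). It was annotated in 87.7%, an ISM in 5.36%, a NIC in 5.70% and an NNC in 1.25%. Of the 70 genes listed for their isoforms, 67 had enough reads, and 28 of the 30 with most reads are described here. Shares are percents of the gene's reads (mean ± SD, n = 2).

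Several neuronal genes used mainly the form with a particular exon. The synaptic fusion gene Snap25 was 86.4% ± 0.397 Snap25-201, which holds the exon at 2:136770057-136770174, and 6.69% ± 0.353 Snap25-202, which holds an alternative exon of the same 118 bases at 2:136769743-136769860. The glycolytic gene Pkm was 86.8% ± 0.514 Pkm-202, with the exon at 9:59675029-59675195, and 8.65% ± 0.236 Pkm-201, with an alternative exon of 167 bases at 9:59675568-59675734. The AMPA receptor gene Gria1 was 62.9% ± 0.104 Gria1-202, with the 115-base exon at 11:57309769-57309883, and 18.1% ± 1.98 Gria1-201, with that at 11:57310608-57310722. Gria2 was 49.4% ± 2.22 Gria2-201 and 23.7% ± 1.19 Gria2-202, which also differ by a pair of 115-base exons. The calcineurin gene Ppp3ca was 54.6% ± 0.322 Ppp3ca-201, with a 30-base exon at 3:136932011-136932040, and 37.5% ± 0.489 Ppp3ca-202, without it. App was 81.1% ± 0.348 App-201, and 3.53% ± 0.194 App-202, which adds the 168-base exon at 16:85043576-85043743. The clathrin light chain gene Cltb was 80.0% ± 0.225 Cltb-201, with a 54-base exon that Cltb-202 (14.8% ± 0.157) lacks. The NMDA receptor gene Grin1 was divided among forms, with Grin1-201 at 27.3% ± 0.261 and Grin1-205 at 20.3% ± 0.783. Cdc42 used different last exons, with Cdc42-201 at 44.4% and 41.7% in replicates 1 and 2 and Cdc42-202 at 28.3% and 31.6%.

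Several glial genes were read mainly as a single form. Apoe was 96.9% ± 0.0168 Apoe-206, Trf was 94.7% Trf-201 in each library, Gfap was 85.3% ± 1.18 Gfap-201 and Clu was 73.5% ± 1.93 Clu-201. Mbp was 66.4% ± 2.12 Mbp-211, and 13.9% and 14.8% in replicates 1 and 2 Mbp-212, which adds the 123-base exon at 18:82578936-82579058. Cnp was 66.1% ± 6.58 Cnp-201. Gnas was 88.1% ± 0.240 Gnas-208, Camk2b 56.1% ± 1.78 Camk2b-209, Map4 47.2% ± 0.816 Map4-206, Rbfox3 42.5% ± 2.29 Rbfox3-204, Atp2b2 35.7% ± 2.06 Atp2b2-203 and Ntrk2 30.7% ± 5.98 Ntrk2-202. The main form was a NIC for Tpm3 (76.9% ± 0.830), Aplp2 (65.5% ± 1.30), Bin1 (35.1% ± 4.33) and Atp2b1 (28.9% ± 2.24) and an NNC for Sptan1 (27.8% ± 0.550). For Cadm1 (43.5% ± 1.02) it was an ISM, part of an annotated chain. For Meg3, pooled single-exon fragments, which are not a single form, had most reads over both libraries. They held 2.00% in replicate 1 and 40.3% in replicate 2 (Fisher's exact test, adjusted p = 1.649e-16). In replicate 1 a NIC held more, 21.3%, against 11.0% in replicate 2. Meg3 was not called with fragments left out.

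**Figure D3:**
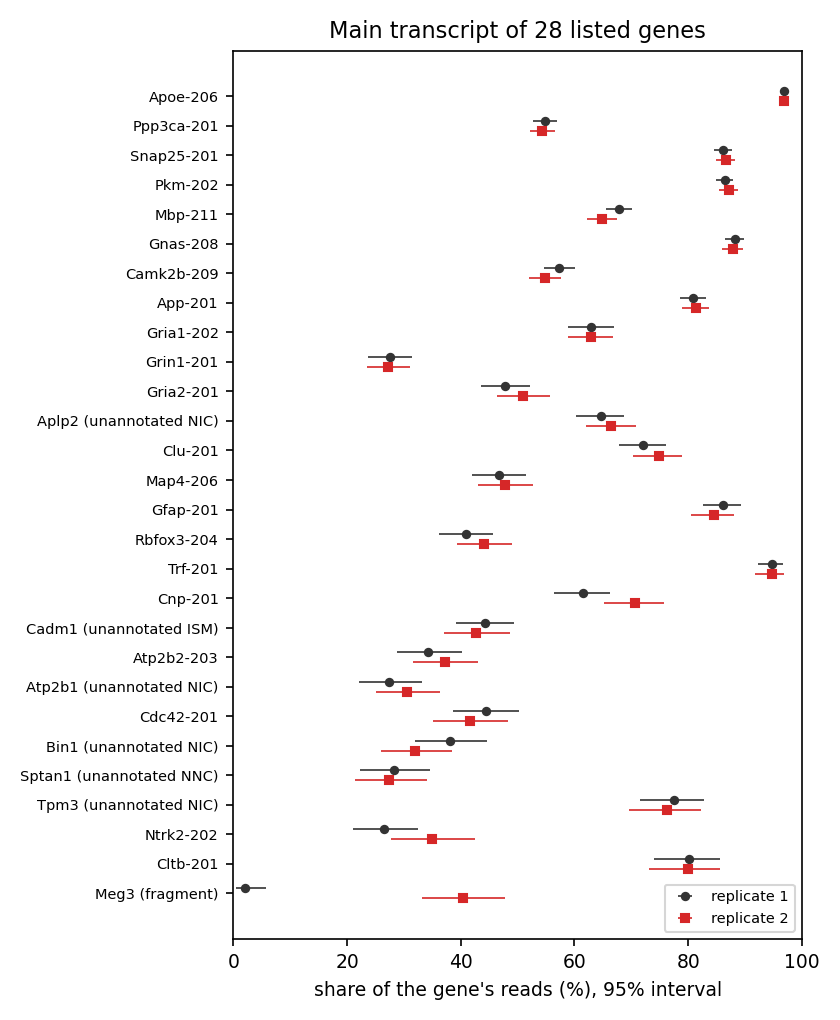
Share of the gene's reads held by its main transcript (x axis, percent) for 28 listed genes (y axis), in replicate 1 (circles) and replicate 2 (squares), with exact 95% intervals. Apoe-206 is highest at 96.9% in both libraries. Meg3, shown by its pooled single-exon fragments, differs most between the libraries, 2.00% against 40.3%.

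In 206 genes, 2 annotated transcripts each held 25 to 60% of the reads in both libraries. Of the 10 with most reads, several differed by a short exon. Eif4h-205 (270 of 540 reads in replicate 1 and 229 of 478 in replicate 2) holds a 60-base exon at 5:134624441-134624500 that Eif4h-201 (42.5% ± 3.01) lacks. Tecr-201 (33.3% ± 3.95) holds 45 bases at 8:83573411-83573455 that Tecr-203 (57.5% ± 0.328) lacks, and Nckap1-202 (42.9% ± 4.50) holds 18 bases at 2:80571213-80571230 that Nckap1-201 (37.4% ± 3.56) lacks. This split is uncertain, since the 16 exons of 16 to 21 bases that every annotated transcript holds had a mean inclusion of only 59.0% and 60.2% in replicates 1 and 2. Ppp3ca, above, was also among them. Others differed at the first exon. Rtn1-201 held 54.5% ± 2.58 and Rtn1-202, which starts upstream, 38.2% ± 1.99, while Abr-203 held 39.0% ± 2.15 and Abr-202 34.9% ± 0.432. Hspa5-201 held 54.0% ± 1.35 and Hspa5-202 43.0% ± 0.594. Olfm1-201 (34.7% ± 1.76) and Olfm1-203 (30.1% ± 1.70) ended in different last exons. Syn1-202 (41.1% ± 5.34) and Syn1-201 (33.2% ± 0.912) joined overlapping last exons at different splice sites, as did Tcf25-202 (38.2% ± 1.89) and Tcf25-208 (37.0% ± 1.31).

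The share of the main transcript differed between the libraries in 113 of the 6179 genes (Fisher's exact test, two-sided, adjusted p under 0.05), higher in replicate 2 for 61 and in replicate 1 for 52. The 5 with the largest excess in replicate 1 were Zbtb7a (85.8% in replicate 1 and 0% in replicate 2), Rab6b (84.9% and 0%), Ywhag (76.9% and 0%), Stmn4 (67.4% and 0%) and Cep19 (63.8% and 0%), all for single-exon fragments. The excess in replicate 2 was largest for Mcee (0% and 88.1%), Camk2a (4.65% and 80.8%) and Syngr1 (4.69% and 71.1%), again for fragments, and was also large for Dynll2-201 (46.4% and 97.2%). Single-exon fragments left out, a setting chosen after seeing the data, 5 genes remained of the 113. These were Atp5b, Ppp2ca, D8Ertd738e, Hnrnpa2b1 and Gprasp2. With annotated transcripts only, Fisher's exact test called 0 of the 3073 genes then tested. With at least 50 reads in each library it called 84 of 3331.

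Unannotated intron chains were numerous, and the highest, apart from that of Rab3a, were the main form of their gene. Of 86643 distinct NIC and NNC chains, 14207 were read in both libraries (16.4%, exact interval 16.2 to 16.6), in 5912 genes. They were 22.2% of the 43675 NIC chains and 10.5% of the 42968 NNC chains, and held 58.0% and 61.4% of the NIC and NNC reads of replicates 1 and 2. In 6295 of the 9687 shared NIC chains every intron was annotated, in a combination that is not. The highest NIC chains were those of Oaz1, an inhibitor of polyamine synthesis (10:80826656-80829284, 867 ± 26.9 CPM, 94.8% of the gene's reads), Apbb1 (7:105558483-105581278, 505 ± 35.9 CPM, 62.0%), Aplp2 (9:31149557-31211815, 351 ± 20.6 CPM, 65.5%), Oaz2 (9:65676548-65690300, 340.3 ± 68.0 CPM, 86.0% and 94.0% in replicates 1 and 2) and Ctbp1 (5:33247723-33274981, 313 ± 13.9 CPM, 56.6%). The Oaz1 and Oaz2 chains equal an annotated transcript once its annotated gap of 4 bases and 1 base, respectively, is closed. The highest NNC chains each had 1 unannotated intron. In Pitpna (350.5 ± 1.77 CPM, 88.5% of the gene's reads) its 5' site lay 4 bases from an annotated site, and in Rab3a (329 ± 27.6 CPM, 27.7%, below Rab3a-201) 1 base. In Trim44 (231 ± 3.25 CPM, 90.8%), Dctn2 (204 ± 37.8 CPM, 81.8%) and Hnrnpk (202 ± 31.0 CPM, 37.1%) the unannotated site lay 16, 10 and 16 bases from an annotated site. Of annotated exons of 9 bases or fewer with at least 20 reads over them in each library, 33 cassette exons and 5 that every annotated transcript holds, none was included in a read.

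Unannotated loci were mainly antisense. Models of unannotated genes formed 38874 loci by overlap on a strand, of which 13587 were seen in both libraries (35.0%, exact interval 34.5 to 35.4). The largest lay opposite Gm26917, an annotated lincRNA (17:39843013-39848827), with 10035 and 8805 reads and 10413 ± 20.2 CPM, above every annotated gene. Only 57.2% of this locus lay over exons of Gm26917, which had 26 and 18 reads in replicates 1 and 2. What RNA the reads of this locus came from was not examined. They are not shown to be an antisense transcript of Gm26917. The next lay opposite Cplx2, which encodes a regulator of vesicle fusion (13:54379548-54383789), wholly within its exons, at 5561 ± 604 CPM, while Cplx2 itself had 376 and 371 reads. Loci opposite Shank1 (7:44356620-44359396, 2657 ± 272 CPM), the glutamate transporter gene Slc1a2 (2:102778106-102789421, 1988 ± 47.9 CPM) and Snhg11 (2:158382148-158384700, 1281 ± 386 CPM) followed. The genes opposite had far fewer reads on their own strand, 65 and 62 for Shank1 and 296 and 213 for Slc1a2. The 3' ends of single-exon antisense models with at least 5 reads were examined only where they lay well inside an annotated exon of the opposite gene, 645 of 3604 models in replicate 1 and 539 of 2532 in replicate 2. Of these, 58.3% and 54.4% had 12 or more A in the 20 bases beyond their 3' end, against 4.36% and 4.32% at random places of the same exons.

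Spike-in RNAs of the Ambion mix took 13571 reads in replicate 1 (1.22%) and 13835 in replicate 2 (1.44%). Of 51 spike-in sequences read, 41 were in both libraries, and log2(reads + 1) had a Pearson r of 0.973 across them. Of the 30 with at least 10 reads in the sum, 2 differed in their share of the spike-in reads (exact binomial test, adjusted p under 0.05).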

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

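With 1 group of 2 libraries, neither library was tested as outlying. Of the tests below, those on multi-exon reads, on reads named for another gene, on choroid plexus markers and on single-exon fragments, and the second draw of random places for the 5' ends, were chosen after the result was seen. The design names no condition, so no biological explanation was tested for these patterns beyond the tissue sampled.

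Of the 62 genes called between the libraries, 44 lost their call with multi-exon reads only. Of these, 24 had fewer than 10 such reads and were not tested, 9 kept the direction and at least 50% of the log2 ratio on fewer reads (Camk2b 0.23 and 0.21), 7 kept the direction with a smaller ratio and 4 turned. At 30 of the 44 another gene held single-exon reads at the same place in the library with fewer; counting all reads there, 26 (86.7%) no longer differed, which is consistent with the same reads carrying another gene's name, while at the other 14, Apoe and Gabarapl1 among them, no such reads lay over the leading single-exon model and the cause stays open. Of the 113 calls on transcript share, leaving fragments out removed 95.6%; 54.0% were higher in replicate 2, but this split says little on truncated reads, since most of these calls rest on fragments, and with chains that lack their 5' part at 6.88% and 7.08% of the reads, more truncated reads in 1 library stay open. Of the 18 gene calls that stayed, 7 (38.9%) passed when the common dispersion was added to counting error, among them Ttr. Spread shared by all genes may account for the others, Cox4i1 and Arc included. That dispersion came from the same 2 libraries, so differences between them are part of it and the test cannot settle this. For Ttr, choroid plexus tissue stays open. The other 3 markers tested had a median log2 ratio of 0.15 and an SD of 0.73, against 1.37 for Ttr.

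Single-exon antisense models took 9.41% of the reads, and those whose 3' end lay well inside an annotated exon of the opposite gene did not end at random places in it; the other models were not examined. In replicate 1, 58.3% of these 645 models, of 3604 with at least 5 reads, had 12 or more A in the 20 bases beyond the 3' end, against 4.36% at random places, and the lower ratio of both libraries was 12.6, which suggests priming on A-rich stretches. In the 480 and 404 models whose 5' end lay between the 3' end and the end of that exon, 5' ends lay within 50 bases of an annotated 3' end of a sense transcript at least 4.99 times as often as random places there, so sense reads given the wrong strand may also contribute; a first draw, on all 645 and 539 models with random places over the whole exon, gave 4.30 and 4.86. A polyadenylation signal before the 3' end was 1.74 times as frequent as at random places, between the bounds set beforehand, so antisense transcripts with their own end remain open.

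Very short exons with enough reads to examine were missing. No read of either library included any of 33 such cassette exons of 9 bases or fewer, against 4961 and 4492 reads that skipped them. Exons that every annotated transcript holds were then tested where at least 20 reads covered them in each library, and those of 9 bases or fewer (5 exons) had a median inclusion of 0% and those of 28 bases or more 100%, which is consistent with a loss in the alignment or the model building. Those of 10 to 15 bases (5 exons) also had a median of 0%, with 1 and 4 including reads in replicates 1 and 2; those of 16 to 21 bases (16 exons) had medians of 91.1% and 94.4% but means of 59.0% and 60.2%, so the loss reached past 15 bases, and those of 22 to 27 bases medians of 99.8% and 98.9%. Chains that equal an annotated transcript without such exons or gaps held 3.10% of the reads of shared unannotated chains, so this may account for a small part of them; chains with splice sites shifted by a lost exon were not searched.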

How the results depend on the processing

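The multi-exon, fragment and common dispersion settings were chosen after seeing the data. The share of annotated reads was 59.4 to 60.2% leaving out each replicate, 59.0% with spike-ins in the total and 65.1% without genomic reads. Genes in both libraries stayed within 1.5 times of the count under 3 alternatives. Pearson r was 0.951 with at least 10 reads, 0.825 with a pseudocount of 0.1 and 0.929 with annotated transcripts only. The coefficient of variation was 6.96% with DESeq2 size factors, 6.96% with no filter and 6.74% with at least 50 reads. Genes that differ numbered 70 under both other scalings and 55 with no filter, but 134 without genomic reads, of which 32 were among the 62 (the cause was not tested), and 18 with annotated transcripts only and 21 with multi-exon reads only, where fewer genes are tested (9069 and 10387), and 32 with the common dispersion added under TMM, where ratios stay as with TMM and the spread allowed is larger. Lists outside the central 95% of random lists numbered 0 in the main setting and 1 with multi-exon reads only (microglia). With at least 50 reads they numbered 4 (microglia, choroid plexus and ependyma, glucocorticoid response, ionotropic glutamate receptor). The choroid plexus list then held only Ttr and Enpp2. The cause of these shifts was not tested. Main transcript calls fell from 113 of 6179 genes to 6 of 5512 without ISM and 0 of 3073 with annotated transcripts only. They numbered 5 of 6078 without fragments and 84 of 3331 with 50 reads in each library. The same main transcript was found in 95.5% of genes without ISM and 96.8% with annotated transcripts only. It was found in 94.2% without fragments and in 95.5% with 50 reads. Chains in both libraries numbered 5622 at 2 reads each, 1923 at 5 reads and 28103 with ISM. The direction turned for Wdr92 with annotated transcripts only (-0.91; the cause was not tested). The alternatives covered 121 results on the genes taken by the naming rule and reported here, or their lists' leading members. Of their values, 751 kept their side of the threshold, 17 lost their call, 9 gained a call and 1 turned. For gene levels, a turn was counted only where the gene was called under either setting. Genes with too few reads, or another main transcript, under a setting gave no value there. Calls lost that way are not among the 17. Leaving 1 library out was run as an alternative only for the share of annotated reads, while results printed per replicate show each library alone. Depth limits genes of few reads, with a median absolute log2 ratio of 0.39 for genes under 50 reads against 0.24 over all genes tested.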

Other observations

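Multi-exon reads also gave the inclusion of annotated cassette exons, as the percent of reads with the exon among those with it or skipping it (mean ± SD, n = 2, at least 20 reads in each library). The exons named here were chosen after their values were seen. The NMDA receptor gene Grin1 included the 63-base exon at 2:25311343-25311405 in 14.9% ± 0.732 of reads and the 111-base exon at 2:25294438-25294548 in 48.2% ± 1.15. In Gria1 the 115-base exon at 11:57309769-57309883 was included in 76.8% ± 2.05 and its partner at 11:57310608-57310722 in 23.2% ± 2.09. In Gria2, on the other strand, the exon at 3:80691320-80691434 was included in 68.5% ± 2.76 and that at 3:80690404-80690518 in 32.9% ± 2.06. In the adhesion gene Cadm1 the 33-base exon at 9:47829377-47829409 was included in 45.4% ± 0.974. In Ncam1, also an adhesion gene, the 30-base exon at 9:49550540-49550569 was included in 62.4% ± 0.954. In Mapt, which encodes tau, the 87-base exon at 11:104287123-104287209 was included in 25.3% ± 8.25.

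A hypothesis set before the result was seen held that exons of 27 bases or fewer are included more than longer ones in hippocampus. The medians were 4.00% for 243 short exons and 98.6% for 8485 longer ones in replicate 1, a lower difference of -94.6 points, the opposite of the prediction. Since the 5 exons of 9 bases or fewer and the 5 of 10 to 15 bases that every annotated transcript holds and that had enough reads had a median inclusion of 0%, the test cannot decide, and it was not repeated on other lengths to obtain a different answer. For cassette exons of 22 to 27 bases the medians were 82.7% and 84.3%.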
